A study of Mus musculus with 32 samples.

How the data were processed

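The deposited values were probe-set intensities on a linear scale, summarised with Affymetrix Expression Console 1.1 per the submitters' processing notes. The summarisation and normalization method was not given in the sources used here. Per the labels, RNA came from a kit extraction and was turned into biotinylated cRNA in a one-cycle protocol before hybridisation. The 32 arrays carried 21350 probe sets used here, with intensities from 2.7 to 19919 and 0 missing values. No deposited column was left unused. Equal values on 2 arrays made up at most 0.703% of the probe sets, and array correlations ran from 0.724 to 0.995.

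Intensities were analysed as log2(value + 16), because the values were not on a log scale. The added 16 damps noise of dim probe sets, and a fold on this scale understates the change of dim genes. Annotation named a gene for 20193 probe sets, 1 gene for 19425 and several for 768, and 1157 had no gene name used here. For genes with more than 1 probe set, 19 in all, the probe set with the highest mean stood for the gene, which left 19405 genes. Among genes with at least 2 called probe sets, signs were opposite for 3 of 10 in the IFNAR-KO against WT comparison and 4 of 14 in the IFNγ-KO against WT comparison. Gene numbers matched the reference for 19384 probe sets, and 0 symbols were changed.

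limma (3.58.1, R 4.3.3) fitted 1 mean per group to all arrays, with empirical Bayes variances and 2-sided tests. p-values were adjusted by Benjamini-Hochberg over all probe sets, and a probe set was called at adjusted p under 0.05. Unstimulated replicates 5 to 8 and 1 to 4 were given separate means where they were compared. Fixed lists were tested with camera at a preset correlation of 0.01 on 30 lists, and again with an estimated correlation. The sex-linked list had 1 measured gene, Xist, and was not tested. List members were also adjusted over the list alone, with limma values and Benjamini-Hochberg. List scores were means over list members of the log2 difference from the unstimulated mean. statmod 1.5.0 served the array weights and the replicate block.

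Genes named per comparison were the 10 largest increases and 5 largest decreases with non-overlapping groups, called chemokines, up to 3 genes per other list with the smallest adjusted p, and a fixed set that was always looked up. The report gives examples from these. Alternatives changed the scaling (quantile normalization, median centring), the variance model (trend and robust, array weights), the samples (only the groups compared, either set of 4 unstimulated arrays, each array left out in turn), the probe sets (the dimmest probe sets left out) and the replicate block. Further alternatives were added after the results were seen: a pseudocount of 1, WT arrays only, retina and lens scores as covariates, and fits without the Xist-low and the low-retina infusion arrays.

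In a self-test, arrays were simulated from the overall mean and fitted variance of each probe set, and 200 probe sets were shifted by known amounts. With the design of day 3 against unstimulated, limma found 80% of shifts of 0.5, 98% of shifts of 1 and 94% of shifts of −1, with 12 false calls. With the design of infusion against PBS it found 36% of shifts of 0.5 and 92% of shifts of 1, with 9 false calls. With the design of the difference of responses it found 34% and 84%, with 9 false calls. The list test found the 1 shifted list and called 0 unchanged lists. Probe sets were simulated independently, so this says nothing about lists of correlated genes.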

Results

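RNA of mouse retinal pigment epithelium and choroid (RPE/choroid), the pigmented layer under the photoreceptors and the vascular layer behind it, was measured on 32 Affymetrix arrays. Unstimulated wild-type (WT) mice gave 8 arrays, and each of the 6 other groups gave 4 arrays. WT mice were sampled at day 3 and at day 8 after systemic infection with lymphocytic choriomeningitis virus (LCMV). Mice lacking the type I interferon receptor (IFNAR-KO) were sampled at day 3, and mice lacking interferon-γ (IFNγ-KO) at day 8. No unstimulated knockout mice were measured. A genotype difference present before infection therefore cannot be told apart from a changed response to infection. Further WT mice were infused with interferon-γ (IFNγ) or with phosphate-buffered saline (PBS). The comparisons asked which chemokine and immune genes changed in this tissue with each stimulus, and which of those changes differed without each interferon pathway. Comparisons, gene lists and rules for naming genes were set before the data were examined. The labels did not state that replicates were separate animals, so the p-values measured only the spread between these samples, which may be technical. The number of arrays limits precision.

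Array-wide intensities separated the knockout arrays from all WT arrays. Upper quartiles were 191 to 229.7 on knockout arrays and 274 to 336 on WT arrays. Lower quartiles were 61.5 to 74.9 on knockout arrays and 43.0 to 53.8 on WT arrays. The first principal component held 63.6% of the variance, with knockout arrays at 73.1 to 109 and WT arrays at −37.7 to −14.5. Xist, transcribed from the inactive X chromosome of female cells, read 71.2 and 34.2 in replicates 1 and 2 of the IFNγ-KO group and 2722 to 4855 on every other array. The photoreceptor score, the mean log2 difference from the unstimulated group, was 0.50 in day 3 replicate 1 and −1.48 to −0.96 in day 3 replicates 2 to 4. In the IFNγ infusion group the photoreceptor score was 0.15 and 0.11 in replicates 1 and 3, and −1.69 and −1.30 in replicates 2 and 4. Its PBS control group averaged −1.03 (SD 0.52, n = 4), so infusion replicates 2 and 4 were nearer their control than replicates 1 and 3.

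**Figure D1:**
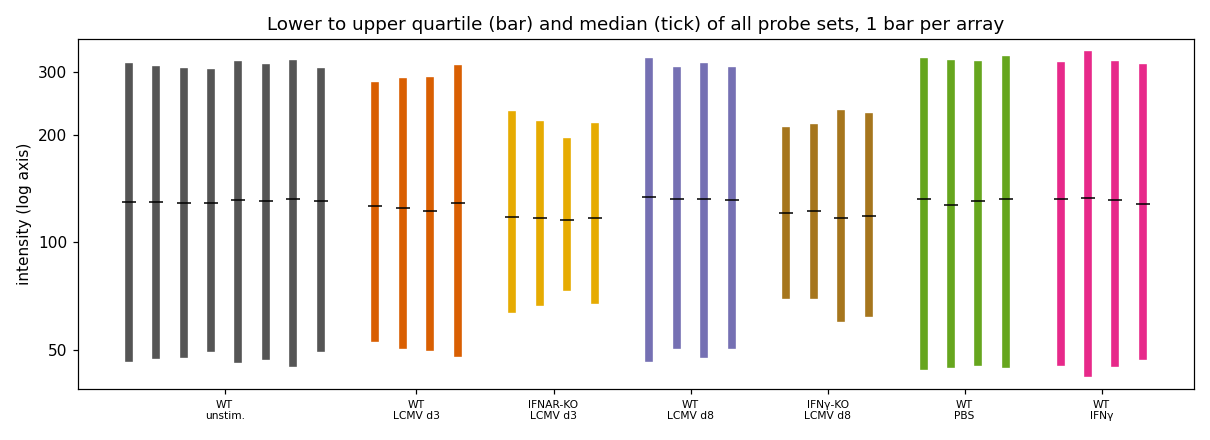
Lower quartile, median and upper quartile of the deposited intensities on each array. Upper quartiles of the knockout arrays were 191 to 229.7 and those of the WT arrays 274 to 336.

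WT tissue at day 3 of LCMV infection was compared with unstimulated WT tissue. Cxcl10, which like Cxcl9 attracts activated T and NK cells through Cxcr3, rose from 125 ± 34.9 (SD, n = 8) to 2182 ± 664 (SD, n = 4), a log2 change of 3.95 (SE 0.27, adjusted p = 1.56e-12). Cxcl9 rose from 85.1 ± 18.6 (SD, n = 8) to 1502 ± 565 (SD, n = 4), a log2 change of 3.84 (SE 0.19, adjusted p = 9.18e-16). Irf7, a transcription factor that amplifies type I interferon production, rose by 3.74 on the log2 scale (SE 0.17, adjusted p = 4.26e-16). Iigp1, an interferon-inducible GTPase that acts against intracellular pathogens, rose by 4.08 (SE 0.17, adjusted p = 1.91e-17). Of 18 measured CC chemokines, 10 rose and 0 fell (11 and 0 adjusted over the list alone). The monocyte attractants Ccl7 and Ccl2 rose by 1.78 (SE 0.15) and 1.69 (SE 0.18), and the T cell attractant Ccl5 by 1.30 (SE 0.15). Of 17 CXC and other chemokines, 5 rose and 0 fell (7 and 0 adjusted over the list alone), among them Cxcl11 at 0.72 (SE 0.11). Cxcl12 (0.44, adjusted p = 0.0959) and Cx3cl1 (0.35, adjusted p = 0.0726) did not pass. Against unstimulated replicates 1 to 4 alone both passed, Cxcl12 at 0.70 (adjusted p = 0.00609) and Cx3cl1 at 0.47 (adjusted p = 0.0191), and with array weights adjusted p = 0.00597 and adjusted p = 0.00199. Against unstimulated replicates 5 to 8 alone the calls of Ccl3 (adjusted p = 0.124), Ccl6 (adjusted p = 0.133), Ccl9 (adjusted p = 0.0888), Ccl22 (adjusted p = 0.102) and Cxcl16 (adjusted p = 0.375) were lost. Without day 3 replicate 2 Ccl6 (adjusted p = 0.0817), Ccl9 (adjusted p = 0.0686), Ccl22 (adjusted p = 0.0524), Cxcl16 (adjusted p = 0.168) and Xcl1 (adjusted p = 0.0754) did not pass, and Ccl22 and Cxcl16 also failed without several other single arrays. Xcl1 also failed without day 3 replicate 3 (adjusted p = 0.0647) and after quantile normalization (adjusted p = 0.167).

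Interferon-response and class I presentation groups rose almost as a whole at day 3. All 29 measured antiviral interferon-stimulated genes rose, with a median log2 change of 2.23, including the RNA-binding Ifit1 (3.00) and the nucleic-acid sensor Zbp1 (3.25). Of 16 IFNγ-induced GTPases and regulators, 15 rose (16 adjusted over the list alone), with Gbp4 at 3.76 and Gbp3 at 3.31. All 14 class I presentation genes rose, with the peptide transporter Tap1 at 2.40 (SE 0.15) and H2-Q4 at 2.65. Of 9 class II presentation genes, 4 rose and 1 fell (7 and 1 adjusted over the list alone), and the list gave adjusted p = 0.212 with an estimated correlation. H2-Ob, which restrains class II peptide loading, was the member that fell (−0.44). Of 24 complement genes, 11 rose and 1 fell (15 and 1 adjusted over the list alone), with Cfb of the alternative pathway at 2.20 (SE 0.18) and C4b at 2.03. Of 23 monocyte and macrophage markers, 13 rose (14 adjusted over the list alone), including the IgG receptors Fcgr4 (2.12) and Fcgr1 (1.86), with adjusted p = 0.0533 with an estimated correlation. Of 25 T and NK cell markers, 8 rose (9 adjusted over the list alone), led by the cytotoxic protease Gzmb at 1.94 (SE 0.16).

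Some markers of lens and retina fell at day 3, and none of these lists kept its call with an estimated correlation. Of 13 lens crystallins 6 fell (12 adjusted over the list alone), with adjusted p = 0.411 with an estimated correlation. Of 23 photoreceptor markers 3 fell (4 adjusted over the list alone), with adjusted p = 0.549 with an estimated correlation. Of 18 inner retina markers 4 fell (5 adjusted over the list alone), with adjusted p = 0.496 with an estimated correlation. Against unstimulated replicates 5 to 8 alone the photoreceptor and inner retina lists did not pass (adjusted p = 0.0711 and adjusted p = 0.0537). The collagen gene Col10a1 fell by 1.41 on the log2 scale (SE 0.16, adjusted p = 5.99e-08), and the neuronal microtubule regulator Stmn2 fell by 1.25 (SE 0.20). Rpe65, the visual-cycle isomerase of the RPE, did not pass (0.16, adjusted p = 0.225), and 1 of 21 RPE genes fell. Rpe65 passed against unstimulated replicates 1 to 4 alone (0.25, adjusted p = 0.0473) and with array weights (0.17, adjusted p = 0.0241). Among smaller groups, 1 of 18 acute phase genes rose, with adjusted p = 0.0649 with an estimated correlation, and 0 of 13 neutrophil markers changed. limma called 1081 probe sets higher and 1391 lower, and camera called 13 lists, of which 7 kept the call with an estimated correlation. After quantile normalization 783 were higher and 360 lower, and after median centring 1509 were higher and 863 lower. The count was 1016 without day 3 replicate 2, 1069 without day 3 replicate 3, 4220 against unstimulated replicates 1 to 4 and 1149 against unstimulated replicates 5 to 8.

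WT tissue at day 8 of infection was compared with the same unstimulated tissue. Ccl5, made by and attracting activated T cells, rose from 140 ± 33.3 (SD, n = 8) to 2376 ± 180 (SD, n = 4), a log2 change of 3.96 (SE 0.15, adjusted p = 5.65e-18). Nkg7, a cytotoxic granule protein, rose by 3.60 (SE 0.15, adjusted p = 1.59e-17), and Cd3g of the T cell receptor complex by 3.54 (SE 0.17, adjusted p = 7.58e-16). Cxcl9 rose by 3.33 (SE 0.19) and Cxcl10 by 2.45 (SE 0.27), and day 8 replicate 1 held the highest Cxcl10 intensity of its group at 1813. Cd74, the class II invariant chain, rose from 723.5 ± 172 (SD, n = 8) to 2445 ± 169 (SD, n = 4), a log2 change of 1.77 (SE 0.18). Ifng itself rose by 0.85 (SE 0.10, adjusted p = 8.87e-08). Of 25 T and NK cell markers, 24 rose, with a median log2 change of 1.38, including Cd8b1 at 2.76 (SE 0.14) and Gzmb at 2.99. Of 18 proliferation genes, 14 rose (17 adjusted over the list alone), with the nuclear division marker Mki67 at 1.96 (SE 0.15) and the cyclin Ccnb2 at 1.52.

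Chemokines and their receptors rose in part at day 8. Of 18 CC chemokines, 5 rose and 0 fell (6 and 1 adjusted over the list alone), with Ccl8 at 1.23 (SE 0.18), Ccl7 at 1.04 and Ccl2 at 0.87. Of 17 CXC and other chemokines, 4 rose and 0 fell, with Cxcl16, the ligand of Cxcr6, at 0.76 (adjusted p = 0.00011). Ppbp, which is in this list, lost its call after quantile normalization (adjusted p = 0.114), without day 8 replicate 4 (adjusted p = 0.394) and in several other fits. Ccl3 lost its call against unstimulated replicates 5 to 8 alone (adjusted p = 0.0578). Cxcl11 (0.19, adjusted p = 0.551) and Ccl12 (0.12, adjusted p = 0.962) did not pass. Of 21 chemokine receptors, 5 rose (6 adjusted over the list alone), with Cxcr6 at 2.56 (SE 0.14), Ccr2 at 1.55 and Cxcr3 at 1.48. Of 9 class II presentation genes 7 rose (8 adjusted over the list alone), and 13 of 14 class I presentation genes rose. Of 16 IFNγ-induced GTPases and regulators, 12 rose (13 adjusted over the list alone), with Iigp1 at 2.43 and Gbp4 at 2.57. Of 29 antiviral genes, 12 rose (19 adjusted over the list alone), with adjusted p = 0.0622 with an estimated correlation. Of 23 monocyte and macrophage markers, 14 rose (17 adjusted over the list alone), with Fcgr4 at 1.71. Of 24 complement genes, 8 rose (11 adjusted over the list alone), with C1qb at 1.12 and C1qc at 1.14, and the list gave adjusted p = 0.0621 with an estimated correlation.

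No single photoreceptor marker or lens crystallin passed at day 8, and Rpe65 did not pass (−0.04, adjusted p = 0.994). The photoreceptor list was lower against unstimulated replicates 1 to 4 alone (−0.64, adjusted p = 0.000116), and the lens list was higher against unstimulated replicates 5 to 8 alone (0.90, adjusted p = 2.3e-05). Of 17 skeletal muscle markers 2 fell (8 adjusted over the list alone), with adjusted p = 0.19 with an estimated correlation. 0 of 12 pigment genes changed, with adjusted p = 0.356 with an estimated correlation. 1 of 13 neutrophil markers rose, with adjusted p = 0.156 with an estimated correlation. limma called 883 probe sets higher and 142 lower, and camera called 18 lists, of which 9 kept the call with an estimated correlation. The split depended on the control arrays. Against unstimulated replicates 1 to 4 alone 1046 were higher and 158 lower. Against replicates 5 to 8 alone 708 were higher and 551 lower.

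Day 8 was also compared with day 3 in WT mice. Irf7 fell from 2096 ± 497 (SD, n = 4) to 373 ± 64.3 (SD, n = 4), a log2 change of −2.42 (SE 0.20, adjusted p = 4.19e-10). Ccl5 was higher at day 8 by 2.66 (SE 0.18, adjusted p = 2.32e-12). Cxcl10 was lower at 858 ± 637 (SD, n = 4) against 2182 ± 664 (SD, n = 4), with adjusted p = 0.00149, while Cxcl9 did not pass (−0.51, adjusted p = 0.149). Cxcl9 was lower without day 3 replicate 1 (−0.80, adjusted p = 0.00681) and with array weights (−0.61, adjusted p = 0.00696). All 29 antiviral genes were lower at day 8, with a median log2 change of −1.79, including Ifit3b (−3.38) and Ifi27l2a (−2.84). Among 16 IFNγ-induced GTPases and regulators 12 were lower (13 adjusted over the list alone). Of 25 T and NK cell markers, 20 were higher and 0 lower (24 and 1 adjusted over the list alone), with Cd3g at 3.41 and Cd8a at 1.87. Of 18 proliferation genes, 11 were higher (16 adjusted over the list alone). Of 18 CC chemokines, 1 was higher and 6 lower (1 and 7 adjusted over the list alone), with adjusted p = 0.281 with an estimated correlation. Ccl7 (−0.75, adjusted p = 0.00522) and Ccl2 (−0.82, adjusted p = 0.0109) were lower, and Ccl8 did not pass (−0.12, adjusted p = 0.796). In a fit of only the groups compared Ccl7 (adjusted p = 0.0583), Ccl2 (adjusted p = 0.0576) and Ccl19 (adjusted p = 0.0695) did not pass. After quantile normalization Ccl12 (adjusted p = 0.0506) and Ccl28 (adjusted p = 0.226) did not pass, and Ccl28 also failed without several single arrays.

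Among 9 class II presentation genes 5 were higher at day 8 (6 adjusted over the list alone), with adjusted p = 0.124 with an estimated correlation, and Cd74 rose by 1.04. Of 14 class I presentation genes 7 were lower (13 adjusted over the list alone), with adjusted p = 0.071 with an estimated correlation. Of 24 complement genes 2 were higher and 6 lower (3 and 6 adjusted over the list alone), with adjusted p = 0.318 with an estimated correlation. The complement genes Cfb and C2 were lower by 1.52 and 1.44 on the log2 scale. Of 21 chemokine receptors 6 were higher, with adjusted p = 0.0864 with an estimated correlation, including Cxcr6 at 2.49 and Ccr2 at 1.75. Apod, a lipid carrier induced in stressed tissue, was lower by 2.47 (SE 0.35), and the collagen-crosslinking enzyme gene Lox was higher by 2.19 (SE 0.25). Of 13 lens crystallins 7 were higher (13 adjusted over the list alone), with adjusted p = 0.3 with an estimated correlation. Of 17 skeletal muscle markers 5 were lower (8 adjusted over the list alone), with adjusted p = 0.318 with an estimated correlation. limma called 1210 probe sets higher and 643 lower. After quantile normalization 593 were higher and 691 lower, and after median centring 823 were higher and 1197 lower. The count was 1061 without day 3 replicate 2, 1228 without day 3 replicate 3 and 1147 without day 8 replicate 1.

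**Figure D2:**
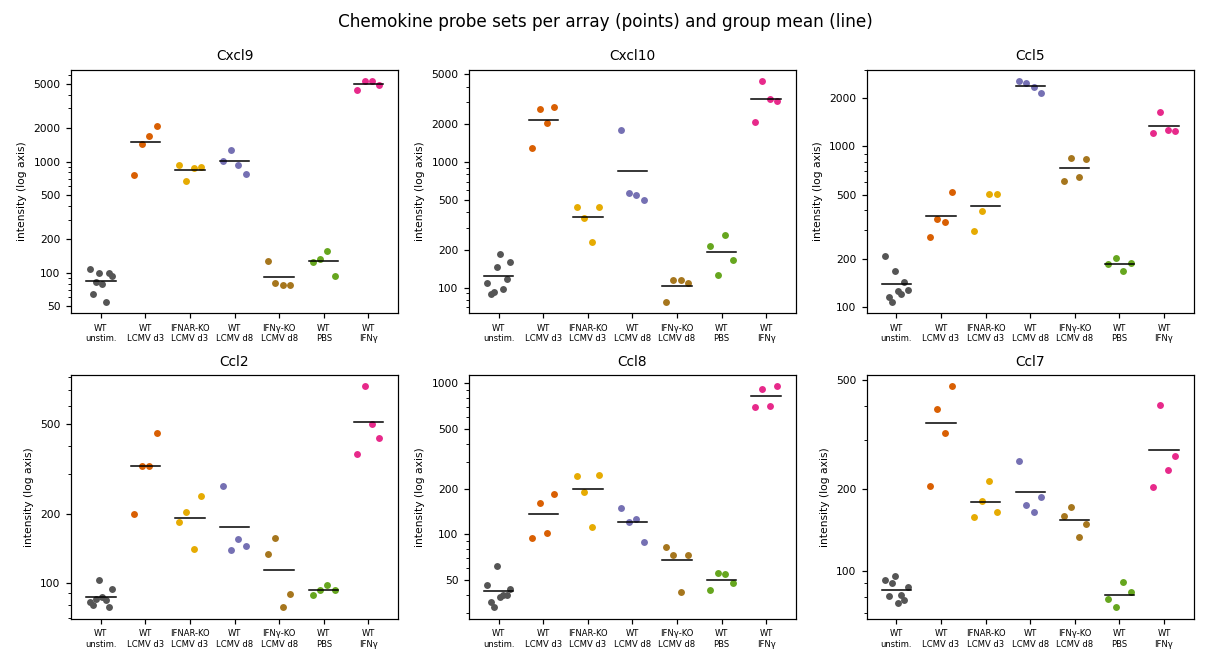
Intensities of chemokine genes on every array by group. Cxcl9 averaged 85.1 in unstimulated, 1502 in WT day 3, 1002 in WT day 8 and 4971 in IFNγ infusion arrays.

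IFNγ infusion was compared with PBS infusion in WT mice to measure the response to the cytokine alone. Cxcl9 rose from 128 ± 26.2 (SD, n = 4) to 4971 ± 429 (SD, n = 4), a log2 change of 5.13 (SE 0.22, adjusted p = 8.52e-17). Cxcl10 rose by 3.95 (SE 0.31, adjusted p = 3.99e-11) and Ccl8, an attractant of monocytes and T cells, by 3.64 (SE 0.20, adjusted p = 2.05e-14). Ccl5 rose by 2.74 (SE 0.18) and Ccl2 by 2.22 (SE 0.21). Of 18 CC chemokines, 7 rose and 0 fell, including Ccl7 at 1.54 (SE 0.17) and the lymphoid chemokine Ccl19 at 1.26. After quantile normalization Ccl6 (adjusted p = 0.0797) and Ccl12 (adjusted p = 0.0813) did not pass. Without infusion replicates 2 and 4 Ccl6 (adjusted p = 0.0711), Ccl12 (adjusted p = 0.204) and Cxcl11 (adjusted p = 0.0728) did not pass. Of 17 CXC and other chemokines, 5 rose and 0 fell (7 and 1 adjusted over the list alone), including Xcl1 at 1.61 and Cxcl16 at 1.02. Cxcl12 (−0.19, adjusted p = 0.852) and Cx3cl1 (0.43, adjusted p = 0.0734) did not pass. Cx3cl1 passed with array weights (adjusted p = 0.000724), in a fit of only the groups compared (adjusted p = 0.0245), with WT arrays only (adjusted p = 0.0133), with a replicate block (adjusted p = 0.0423) and without PBS replicate 2 (adjusted p = 0.049). All 16 IFNγ-induced GTPases and regulators rose, with a median log2 change of 2.97, including Iigp1 at 4.32 (SE 0.19), Gbp4 at 4.15 and Irf1 at 2.57. All 9 class II presentation genes rose, including their regulator Ciita at 2.13 and Cd74 at 2.17 (SE 0.20). All 14 class I presentation genes rose, with Tap1 at 2.98 (SE 0.17). Of 29 antiviral genes, 27 rose (29 adjusted over the list alone), with a median log2 change of 1.33, including Irf7 at 2.41 and Zbp1 at 2.80.

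Immune-cell and complement genes rose with IFNγ infusion too. T and NK cell markers rose for 18 of 25, led by the NK cell receptor Ncr1 at 2.43 (SE 0.13), Nkg7 at 2.40 and Il2rb at 2.20. Of 23 monocyte and macrophage markers, 12 rose and 0 fell (15 and 1 adjusted over the list alone), with Fcgr4 at 3.03 and Aif1 at 1.67. Fcrls and Cd5l, expressed by resident macrophages, fell by 2.12 (SE 0.23) and 1.70 (SE 0.27) on the log2 scale. Dnase1l3 (3.94, SE 0.18) and Xcr1 (1.97), expressed by dendritic cells, rose. Of 24 complement genes, 10 rose and 0 fell (11 and 1 adjusted over the list alone), with Cfb at 1.69, C4b at 1.64 and C1ra at 1.43. Of 18 proliferation genes 10 rose (14 adjusted over the list alone), with Mki67 at 1.31. Of 8 endothelial adhesion molecules 3 rose, with adjusted p = 0.0733 with an estimated correlation, including Vcam1 at 1.09 and Madcam1 at 1.75. Of 18 acute phase genes 5 rose (7 adjusted over the list alone), 2 of 13 neutrophil markers rose (4 adjusted over the list alone), and 4 of 21 chemokine receptors rose (6 adjusted over the list alone).

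Some pigment, matrix, pericyte and angiogenic genes fell with IFNγ infusion. Of 12 pigment genes 7 fell (9 adjusted over the list alone), with adjusted p = 0.0553 with an estimated correlation. Pmel, which forms the fibrils of pigment granules, fell from 2705 ± 246 (SD, n = 4) to 1069 ± 386 (SD, n = 4), a log2 change of −1.38 (SE 0.22, adjusted p = 4.75e-05). The melanin-synthesis genes Tyrp1 (−0.85, SE 0.18) and Oca2 (−0.59) fell as well. Of 21 RPE genes 3 fell (5 adjusted over the list alone), with adjusted p = 0.205 with an estimated correlation, including Ermn (−0.92), while Rpe65 did not pass (−0.22, adjusted p = 0.197). With array weights Rpe65 was lower (−0.28, adjusted p = 0.000185). Of 15 scleral and fibroblast matrix genes 7 fell (12 adjusted over the list alone), with adjusted p = 0.113 with an estimated correlation. Of 11 pericyte and smooth muscle markers 4 fell (10 adjusted over the list alone), with the contractile gene Cnn1 at −0.94. Of 13 angiogenic factors 3 fell (6 adjusted over the list alone), with adjusted p = 0.0801 with an estimated correlation, including Esm1 (−1.56, SE 0.24) and Angpt1 (−1.20). 0 of 16 endothelial markers changed, with adjusted p = 0.321 with an estimated correlation. 0 of 13 lens crystallins and 1 of 23 photoreceptor markers changed, with adjusted p = 0.327 and adjusted p = 0.538 with an estimated correlation. limma called 951 probe sets higher and 628 lower, and camera called 24 lists, of which 14 kept the call with an estimated correlation.

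PBS infusion was compared with unstimulated WT tissue as a control for the infusion. limma called 0 probe sets, and 3700 had an unadjusted p under 0.05. The 0 calls depended on the setting. Calls at adjusted p under 0.05 numbered 3989 against unstimulated replicates 1 to 4 alone, 4625 with array weights and 3405 with a replicate block. Cxcl9 (0.51, SE 0.19, adjusted p = 0.165) and Cxcl10 (0.56, adjusted p = 0.274) did not pass. Ccl5 (0.40, adjusted p = 0.182) and Cd74 (0.51, adjusted p = 0.145) did not pass either. With array weights all of these passed, Cxcl9 with adjusted p = 0.00771, Cxcl10 with adjusted p = 0.0262, Ccl5 with adjusted p = 0.019 and Cd74 with adjusted p = 0.0106. Against unstimulated replicates 1 to 4 alone Cd74 was higher by 0.77 (adjusted p = 0.00434). Of 23 photoreceptor markers 19 fell when adjusted over the list alone, with adjusted p = 0.293 with an estimated correlation. Of 23 monocyte and macrophage markers 15 rose when adjusted over the list alone, with adjusted p = 0.293 with an estimated correlation. Unstimulated replicates 5 to 8 were compared with unstimulated replicates 1 to 4, because the labels numbered the 8 arrays in one series. The class II gene H2-Eb1 was higher by 0.66 (SE 0.14, adjusted p = 0.00451) in replicates 5 to 8, while Cxcl9 (−0.11, adjusted p = 0.861) and Rpe65 (0.19, adjusted p = 0.218; adjusted p = 0.0282 with array weights) did not pass. H2-Eb1 did not pass with retina and lens covariates (0.49, adjusted p = 0.0783). Of 23 monocyte and macrophage markers 9 were higher (15 adjusted over the list alone), with adjusted p = 0.278 with an estimated correlation. Of 13 lens crystallins 3 were lower (8 adjusted over the list alone), with adjusted p = 0.307 with an estimated correlation. limma called 906 probe sets higher and 530 lower. The count was 476, 849, 745, 503, 625 and 680 without unstimulated replicates 2, 3, 4, 6, 7 and 8.

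The response to IFNγ infusion over PBS was compared with the response to infection at day 8 over unstimulated tissue. Ccl8 responded more to infusion by 2.41 (SE 0.27, adjusted p = 7.89e-07), Cxcl9 by 1.80 (SE 0.29, adjusted p = 0.000217) and Ccl2 by 1.35 (SE 0.28, adjusted p = 0.005). Ccl5 responded less to infusion (−1.22, SE 0.23, adjusted p = 0.00208). The T cell receptor gene Cd3g (−2.38, SE 0.26, adjusted p = 6.38e-07) and Cd8a (−1.60) responded less as well. Of 25 T and NK cell markers, 2 responded more and 14 less (3 and 16 adjusted over the list alone). All 16 IFNγ-induced GTPases and regulators responded more to infusion, with a median difference of 1.57, including Gbp2b at 3.31 (SE 0.26) and Iigp1 at 1.89. Of 29 antiviral genes 11 responded more (20 adjusted over the list alone), and 9 of 14 class I presentation genes responded more (13 adjusted over the list alone). Among 9 class II presentation genes 2 responded more (4 adjusted over the list alone), while Cd74 did not pass (0.40, adjusted p = 0.867; 0.48, adjusted p = 0.0452 with array weights). Of 18 CC chemokines 3 responded more and 1 less (4 and 1 adjusted over the list alone), with adjusted p = 0.13 with an estimated correlation. limma called 152 probe sets with a larger and 166 with a smaller response to infusion, 112 and 83 after quantile normalization, and 158 and 140 after median centring. The count was 198 without IFNγ infusion replicate 3.

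IFNAR-KO tissue at day 3 was compared with WT tissue at day 3, both after infection, to find genes that differ between these genotypes. Ifnar1, the targeted gene, read 93.6 to 144 on the 4 IFNAR-KO arrays and 304 to 390.4 on the WT day 3 arrays, a log2 change of −1.53 (SE 0.11, adjusted p = 9.36e-13). A probe outside the deleted part checks nothing, and the position of this probe set was not known here. limma called 8515 probe sets higher and 6895 lower, 72.2% of all, beside the array-wide difference in quartiles given above. The median log2 change of all probe sets was 0.09 to 0.11 in the 4 knockout comparisons, but this hides a narrower spread on knockout arrays. Their interquartile range on the log2 scale was 1.19 to 1.66, against 2.05 to 2.58 on WT arrays. A shift by 1 constant therefore does not describe the array-wide difference. Irf7 was lower at 116 ± 32.1 (SD, n = 4) against 2096 ± 497 (SD, n = 4), with adjusted p = 1.04e-16. Usp18, which dampens the type I interferon receptor, was lower by 3.72 (SE 0.21, adjusted p = 1.08e-15). Cxcl10 was lower by 2.50 (SE 0.31, adjusted p = 3.04e-08), at 369 ± 98.4 (SD, n = 4) against 2182 ± 664 (SD, n = 4). Cxcl9 was lower by 0.75 (SE 0.22, adjusted p = 0.00276), with adjusted p = 0.173 after quantile normalization. Ccl7 was lower by 0.85 (adjusted p = 8.89e-05), while Ccl5 (0.20, adjusted p = 0.297) and Cxcl11 (−0.16, adjusted p = 0.275) did not pass. After quantile normalization Ccl5 was higher in IFNAR-KO tissue by 0.65 (adjusted p = 0.00241), and without WT day 3 replicate 1 Cxcl11 was lower (−0.30, adjusted p = 0.0356). Among the largest increases were the mitochondrial gene Cox17 at 4.14 (SE 0.10) and the noncoding RNA Gas5 at 3.53.

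Gene groups in the IFNAR-KO comparison have to be read beside that array-wide difference. Over all probe sets 8515 were called higher and 6895 lower, 72.2% of all. Counts of list members were not tested against this background. A count alone, such as those of both chemokine lists, is therefore no evidence of a knockout effect. Of 29 antiviral genes 28 were lower and 0 higher, with adjusted p = 1.07e-10, and with adjusted p = 0.56 with an estimated correlation. Of 14 class I presentation genes 2 were higher and 11 lower, with adjusted p = 0.571 with an estimated correlation, and Tap1 was lower by 2.15. Of 16 IFNγ-induced GTPases and regulators 2 were higher and 9 lower, with Irgm1 at −1.56 and Irf1 at −2.21. Of 18 CC chemokines 9 were higher and 4 lower, with the macrophage chemokine Ccl3 at −2.15 (SE 0.34) and the eosinophil attractant Ccl11 at 0.90. Of 17 CXC and other chemokines 7 were higher and 5 lower, with Cx3cl1 at −1.43 and Cxcl16 at −1.09. Of 21 RPE genes 2 were higher and 18 lower, with adjusted p = 0.56 with an estimated correlation. Of 15 matrix genes 14 were lower, with adjusted p = 0.56 with an estimated correlation, including Bgn (−2.78, SE 0.14). Of 16 endothelial markers 1 was higher and 13 lower, with adjusted p = 0.571 with an estimated correlation. Among 25 T and NK cell markers 15 were higher and 1 lower, with adjusted p = 0.571 with an estimated correlation. The complement gene C1qb was lower by 2.67 (SE 0.19), and Cfb by 1.41. After quantile normalization the class I list (adjusted p = 0.214) and the T and NK cell list (adjusted p = 0.469) lost their calls. camera called 11 lists, of which 0 kept the call with an estimated correlation.

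IFNγ-KO tissue at day 8 was compared with WT tissue at day 8, both after infection, to find genes that differ between these genotypes. Ifng, the targeted gene, read 82.9 to 112 on the 4 IFNγ-KO arrays and 88.4 to 122.5 on the WT day 8 arrays, and did not pass (−0.05, SE 0.11, adjusted p = 0.693). A probe outside the deleted part checks nothing, and the position of this probe set was not known here, so the reading leaves the genotype labels unchecked. Cxcl9 was lower by 3.25 on the log2 scale (SE 0.22, adjusted p = 4.68e-14), at 90.9 ± 24.3 (SD, n = 4) against 1002 ± 209 (SD, n = 4). Cxcl10 was lower by 2.65 (SE 0.31, adjusted p = 9.69e-09) and Ccl5 by 1.69 (SE 0.18, adjusted p = 9.48e-10). Ccl8 was lower by 0.73 (adjusted p = 0.00235), while Ccl7 (−0.30, adjusted p = 0.121) and Cxcl11 (−0.07, adjusted p = 0.657) did not pass. Cd74 was lower by 4.55 (SE 0.20, adjusted p = 5e-18), at 90.8 ± 20.9 (SD, n = 4) against 2445 ± 169 (SD, n = 4). Iigp1 was lower by 2.28 (SE 0.19) and Gbp4 by 2.91. S100a8 and S100a9, calcium-binding proteins of neutrophils, were higher by 2.77 (SE 0.16, adjusted p = 2.36e-15) and 2.71. Ifnar1 was lower here too (−0.82, SE 0.11, adjusted p = 2.6e-07). Cox17 was higher by 4.56 (SE 0.10) and Gas5 by 4.35.

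Gene groups in the IFNγ-KO comparison have to be read in the same way. Over all probe sets 8328 were called higher and 7034 lower, 72.0% of all. Counts of list members were not tested against this background, so a count alone is no evidence of a knockout effect. Of 9 class II presentation genes 7 were lower and 0 higher, with adjusted p = 0.608 with an estimated correlation, including H2-Eb1 at −2.82 and H2-DMa at −2.24. Of 16 IFNγ-induced GTPases and regulators 1 was higher and 12 lower, with adjusted p = 0.608 with an estimated correlation. Of 29 antiviral genes 15 were lower (13 adjusted over the list alone), with adjusted p = 0.651 with an estimated correlation. Among 25 T and NK cell markers 3 were higher and 16 lower, with adjusted p = 0.608 with an estimated correlation, including Nkg7 at −2.17, Cd8a at −1.40 and Gzmk at −1.33. Of 18 CC chemokines 9 were higher and 4 lower, with the CC chemokines Ccl11 and Ccl12 at 1.38 and 1.20 and Ccl3 at −2.00. Of 17 CXC and other chemokines 9 were higher and 4 lower, with Cxcl16 at −1.60 and Cx3cl1 at −1.21. Of 13 neutrophil markers 9 were higher and 3 lower, with adjusted p = 0.608 with an estimated correlation. After quantile normalization the antiviral list read −0.11 (adjusted p = 0.122) and lost its call, as did the neutrophil list (adjusted p = 0.27) and the class I list (adjusted p = 0.0791). Of 18 proliferation genes 3 were higher and 12 lower, with Mki67 at −1.42. Of 21 RPE genes 2 were higher and 18 lower, with adjusted p = 0.608 with an estimated correlation. Of 15 matrix genes 13 were lower, and of 13 lens crystallins 10 were lower, with adjusted p = 0.608 and adjusted p = 0.618 with an estimated correlation. Rpe65 was lower by 0.43 (adjusted p = 0.000203), and read 0.09 (adjusted p = 0.277) after quantile normalization. limma called 8328 probe sets higher and 7034 lower, and camera called 13 lists, of which 0 kept the call with an estimated correlation.

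Both knockout groups were also compared with unstimulated WT tissue. In IFNAR-KO tissue at day 3, Cxcl9 was higher by 3.09 (SE 0.19, adjusted p = 3.4e-15), Iigp1 by 4.20 (SE 0.17, adjusted p = 1.53e-19) and Cxcl10 by 1.45 (SE 0.27, adjusted p = 1.46e-05). Irf7 did not pass in the IFNAR-KO group (−0.26, adjusted p = 0.168), and neither did Ifit1 (−0.09, adjusted p = 0.647). After quantile normalization Ifit1 turned to 0.46 (adjusted p = 0.0282), and the antiviral list was called higher at 0.51 (adjusted p = 0.00337). In IFNγ-KO tissue at day 8, Cxcl9 (0.08, adjusted p = 0.707), Cxcl10 (−0.21, adjusted p = 0.487) and Iigp1 (0.16, adjusted p = 0.397) did not pass. Ccl5 was higher in both, at 427 ± 101 (SD, n = 4) in IFNAR-KO tissue (adjusted p = 3.35e-10) and by 2.27 (SE 0.15, adjusted p = 3.89e-14) in IFNγ-KO tissue. Cd3g was higher by 2.42 (SE 0.17, adjusted p = 1.66e-13) in IFNγ-KO tissue at day 8. Of 25 T and NK cell markers 22 were higher in IFNAR-KO tissue and 23 in IFNγ-KO tissue, with adjusted p = 0.527 and adjusted p = 0.201 with an estimated correlation. Scores of other marker lists moved as well in these 2 groups. B cell (0.44 and 0.52), erythroid (0.57 and 0.43) and neutrophil scores (0.71 and 0.88) were higher. Endothelial (−0.98 and −0.96) and matrix scores (−1.30 and −1.22) were lower. Of 16 IFNγ-induced GTPases and regulators 12 were higher and 1 lower in IFNAR-KO tissue, with adjusted p = 0.527 with an estimated correlation. In IFNγ-KO tissue 3 of those 16 genes were higher and 6 lower. Cd74 was lower than in unstimulated tissue in both, by 1.04 and 2.77 on the log2 scale. S100a9 was higher by 1.84 in IFNAR-KO tissue and by 2.82 in IFNγ-KO tissue. limma called 17180 and 16310 probe sets, with 9410 and 8972 higher and 7770 and 7338 lower. Counts of list members were not tested against this background either. camera called 13 and 12 lists, of which 0 kept the call with an estimated correlation.

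**Figure D3:**
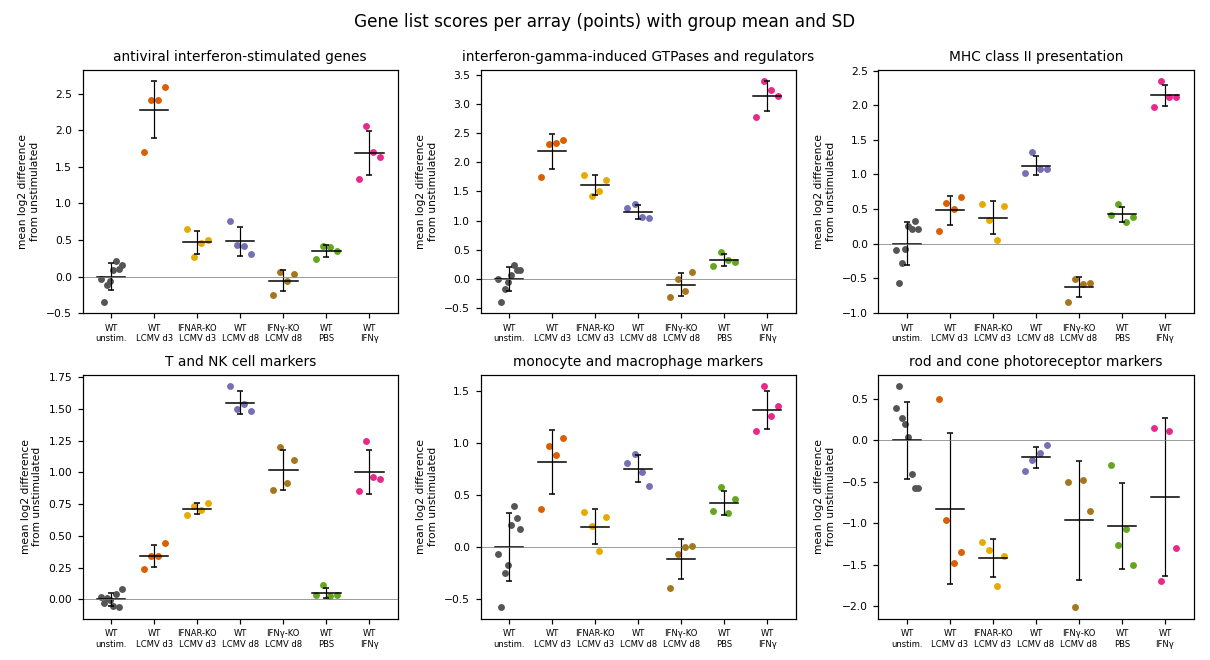
Mean log2 difference from the unstimulated group over each gene list, for every array. The photoreceptor score was 0.50 in day 3 replicate 1 and −1.48 to −0.96 in replicates 2 to 4.

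Shared responses were counted between comparisons with separate or shared controls. Of 1081 probe sets higher at day 3, 453 were also higher with IFNγ infusion, where 48.2 would be shared by independent calls. Of 883 probe sets higher at day 8, 559 were also higher with infusion, where 39.3 would be shared by independent calls. Day 3 and day 8 shared 351 higher probe sets with all unstimulated arrays as control of both. With unstimulated replicates 1 to 4 as control for one and 5 to 8 for the other, they shared 271 and 233, where 54.0 and 27.9 would be shared by independent calls. Lower calls shared in the same fits numbered 11 and 16, where 66.9 and 4.28 would be shared by independent calls. Correlations over all probe sets were −0.00067 and 0.364 in these fits. With all unstimulated arrays as control of both the correlation was 0.416, where simulated data without any change gave 0.331. Probe sets higher at day 3 and lower in IFNAR-KO than in WT tissue were counted with separate WT day 3 arrays in each comparison. They numbered 260 and 315 in both ways of separating the arrays, where 179 and 178 would be shared by independent calls. The same count for day 8 and IFNγ-KO tissue gave 382 and 321, where 166 and 131 would be shared by independent calls. Correlations over all probe sets were 0.069 and 0.0082 in the day 3 fits and −0.276 and −0.248 in the day 8 fits. The numbers for independent calls take no account of the array-wide difference of the knockout arrays. limma detected no WT response at 12359 probe sets, with unadjusted p above 0.05 at day 3, at day 8 and with infusion. Of these, 76.6% were called in the IFNAR-KO comparison and 72.7% in the IFNγ-KO comparison. Log2 changes of those probe sets in both knockout comparisons correlated at 0.908.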

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

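Single arrays and counts were set apart by a fixed rule, and chance alone sets apart about 1 in 20 groups by it. The rule was applied to 56 groups of array measures, 217 groups of list scores and 126 groups of gene intensities, and set apart 1, 10 and 9 of them. IFNAR-KO replicate 3 had a mean correlation of 0.902 with its group, against 0.939 to 0.940 for the others.

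Scores of lists stood apart on these arrays. Day 3 replicate 1 scored 1.75 for IFNγ-induced GTPases (others 2.32 to 2.38), 0.30 for complement (others 0.68 to 0.72) and 0.10 for inner retina (others −0.76 to −0.69). PBS replicate 2 scored 0.47 for class I presentation (others 0.23 to 0.27), 0.37 for endothelial adhesion (others 0.08 to 0.10) and 0.11 for T and NK cells (others 0.02 to 0.03). PBS replicate 3 scored 0.13 for CC chemokines. Day 8 replicate 1 scored 0.32 for Schwann cell and myelin markers (others −0.28 to −0.22), and IFNγ-KO replicate 3 scored −0.89 (others −0.78 to −0.77). IFNAR-KO replicate 2 scored 0.28 for proliferation (others 0.47 to 0.51).

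Chemokine intensities stood apart on these arrays. Day 8 replicate 1 read 1812.7 for Cxcl10 (others 500.2 to 571), 113.1 for Cxcl11 (others 83.5 to 85.0), 266.5 for Ccl2 (others 139 to 155) and 51.2 for Ccl12 (others at most 35). IFNγ-KO replicate 1 read 127.3 for Cxcl9 (others 77.5 to 81.0) and 76.7 for Cxcl10 (others 109 to 115.5). Infusion replicate 2 read 1630.8 for Ccl5 (others 1205 to 1271), unstimulated replicate 4 read 61.4 for Ccl8 (others 32.9 to 46.0), and day 3 replicate 1 read 56.9 for Ccl12 (others 88.2 to 93.6).

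Probe sets were called in each comparison of one difference with another: 1853 between day 8 and day 3, 318 between the infusion and day 8 responses, and 2907 between both knockout differences.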

How the results depend on the processing

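Alternatives marked as added in the processing text were chosen after the results were seen, as were the 2 knockout contrasts. Where a value moved, the cause was not tested. For named genes the call status (adjusted p under 0.05 or not) was unchanged in 7922 refits, lost in 209 and gained in 78. In 3 the sign turned, with a call before or after. For lists these numbers were 9030, 417, 243 and 4. An unchanged call status does not mean that the size of a change stayed the same. Counts of probe sets stayed within 1.5 times in 736 settings and moved in 197, and counts of lists stayed in 302 and moved in 22. Intensity of dim probe sets is mostly background, so a change there reads smaller than it was.

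Replicate numbers gave no clear pairing of the groups: 0 to 2 of 4 arrays of a group best matched the array of their own number. With so few arrays this cannot exclude pairing. For infusion and PBS, deviations from the group mean correlated at −0.0058 to 0.714 for the same number and −0.591 to 0.505 for other numbers. The replicate block also takes unstimulated replicates 5 to 8 out of every contrast, because no other group has these numbers. With it the day 3 count was 3704 and PBS against unstimulated 3405, beside 4220 and 3989 with unstimulated 1 to 4 as control and no block. The block left the other counts within 1.5 times, and moved the monocyte list to −0.23 (adjusted p = 0.478) in infusion minus day 8.

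Array weights: 7566 (day 3), 3047 (day 8), 7555 (day 8 against day 3), 6171 (infusion), 4625 (PBS against unstimulated), 6538 (unstimulated replicates), 2887 (infusion minus day 8), 798 with 5 lists (knockout against knockout), 1866 (difference of knockout differences). WT arrays only: 5574 (day 3), 1934 (day 8), 4309 (day 8 against day 3), 2894 (infusion), 1 (PBS), 4151 (unstimulated replicates), 688 (infusion minus day 8). Only the groups compared: 1752 (day 8), 3109 (day 8 against day 3), 3159 (infusion), 5121 (unstimulated replicates), 868 (infusion minus day 8), 116 (knockout against knockout), 788 (difference of knockout differences).

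Change of at least 1 on the log2 scale: 272 (day 3), 226 (day 8), 266 (day 8 against day 3), 3815 (IFNAR-KO against WT), 4409 (IFNAR-KO against unstimulated), 3843 (IFNγ-KO against WT), 3610 (IFNγ-KO against unstimulated), 411 (infusion), 67 (unstimulated replicates), 159 (infusion minus day 8), 113 (knockout against knockout), 362 (difference of knockout differences). Dimmest probe sets left out: 9651 with 6 lists (IFNAR-KO against WT), 10886 (IFNAR-KO against unstimulated), 10122 with 1 list (IFNγ-KO against WT), 10651 with 6 lists (IFNγ-KO against unstimulated), 2022 (knockout against knockout), 1809 (difference of knockout differences).

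Estimated correlation, lists called: 7 of 13 (day 3), 9 of 18 (day 8), 4 of 12 (day 8 against day 3), 0 of 11 (IFNAR-KO against WT), 0 of 13 (IFNAR-KO against unstimulated), 0 of 13 (IFNγ-KO against WT), 0 of 12 (IFNγ-KO against unstimulated), 14 of 24 (infusion), 0 of 15 (PBS), 0 of 18 (unstimulated replicates), 7 of 22 (infusion minus day 8), 1 of 12 (knockout against knockout).

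Quantile normalization: 1143 (day 3), 845 (unstimulated replicates), 195 (infusion minus day 8), 6 lists (IFNAR-KO against WT). Under it Ifit1 read 0.46 (adjusted p = 0.0282, IFNAR-KO against unstimulated), Rpe65 0.0918 (adjusted p = 0.277, IFNγ-KO against WT) and Gbp3 0.0273 (adjusted p = 0.892, IFNγ-KO against unstimulated). Retina and lens covariates: 976 (day 3), 475 (unstimulated replicates), 7 lists (PBS), 7 lists (knockout against knockout), and the matrix list at −0.0102 (PBS). Unstimulated 1 to 4 as control: 4220 (day 3), 3989 (PBS), 489 (infusion minus day 8), with the monocyte list at −0.23 (infusion minus day 8). Unstimulated 5 to 8 as control: 1149 (day 3). Without the 2 low-retina infusion arrays the immediate early and heat shock list read −0.0569. That fit keeps the infusion arrays whose photoreceptor score was further from the PBS mean.

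Leaving out single arrays gave 1016 to 2830 (day 3), 1061 to 2138 (day 8 against day 3), 476 to 1399 (unstimulated replicates) and 198 to 315 (infusion minus day 8). Lists ran from 7 (without IFNAR-KO replicate 3 or IFNγ-KO replicate 1) to 11 for knockout against knockout, and from 5 to 8 (without day 3 replicate 2) for the difference of knockout differences.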

Other observations

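Both knockout groups were also compared with each other, a contrast added after the results were seen. Cxcl9 was higher in IFNAR-KO tissue at day 3 than in IFNγ-KO tissue at day 8 by 3.01 (SE 0.22, adjusted p = 2.76e-11), and Iigp1 by 4.04 (SE 0.19, adjusted p = 2.51e-15). Irf7 (0.11, adjusted p = 0.751) and Usp18 (−0.12, adjusted p = 0.725) did not pass. Of 16 IFNγ-induced GTPases and regulators 12 were higher (13 adjusted over the list alone), with adjusted p = 0.0467 with an estimated correlation. Of 9 class II presentation genes 6 were higher, with adjusted p = 0.239 with an estimated correlation, including Cd74 at 1.73 and H2-Eb1 at 1.46. limma called 2584 probe sets higher and 1636 lower, but only 116 in a fit of only the groups compared.

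The knockout difference at day 3 was compared with the knockout difference at day 8, also added after the results were seen. Genotype and day differ together in this contrast, so neither can be credited alone. Irf7 (−2.31, SE 0.29, adjusted p = 3.32e-06), Usp18 (−2.22) and Ifit1 (−1.26) had the lower knockout difference at day 3. WT Irf7 was itself higher at day 3, and Irf7 did not pass between both knockout groups. Cxcl9 (2.50, SE 0.31, adjusted p = 2.69e-06), Cd74 (2.77, SE 0.29, adjusted p = 2.55e-07) and Ccl5 (1.89, adjusted p = 7.07e-06) had the lower knockout difference at day 8. Ccl5 was not called lower in IFNAR-KO tissue at day 3, and WT Ccl5 was itself higher at day 8. Cxcl10 (0.16, adjusted p = 0.855) and Ccl2 (−0.12, adjusted p = 0.832) did not pass. Of 29 antiviral genes 22 had the lower difference at day 3 (27 adjusted over the list alone), with adjusted p = 0.0423 with an estimated correlation. Of 9 class II presentation genes 6 had the lower difference at day 8 (8 adjusted over the list alone), with adjusted p = 0.0292 with an estimated correlation. limma called 1798 probe sets higher and 1109 lower, but only 788 in a fit of only the groups compared. After quantile normalization 1433 were higher and 1668 lower, and after median centring 1417 were higher and 1387 lower.

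Both knockout groups differed from WT at most probe sets, and the 3 tests of this were chosen after the result was seen. Of the 12359 probe sets without a detected WT response, 63.1% were called in both knockout comparisons with WT. This argues against the hypothesis of lost interferon signalling alone, although small WT responses may have gone undetected. The correlation of 0.908 between both knockout differences goes with the hypothesis of a difference common to all knockout arrays, such as processing batch or strain background, which could not be tested here. Without the 2 Xist-low arrays 12564 probe sets were called in IFNγ-KO against WT, which argues against sex as the explanation. What share of each named change comes from the common difference stays open.

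Unstimulated replicates 5 to 8 differed from 1 to 4. The retina test was set before and the shared-batch test after the result was seen. Of the called probe sets 52.2% followed the photoreceptor score in the direction of their own change, which goes with the hypothesis of retina carried over. For other probe sets only 1 fixed direction was counted (12.9%), so that share is no like background for the 52.2%. Day 3 calls numbered 4220 against replicates 1 to 4 and 1149 against 5 to 8. The photoreceptor list was lower in replicates 5 to 8 than in 1 to 4 (median −0.71), and the mean photoreceptor score at day 3 was −0.82. Retina content alone could therefore set these counts, which leaves a batch shared by replicates 1 to 4 and the day 3 arrays undecided. Day 8 calls numbered 1204 and 1259, of which 158 and 551 were lower, which leaves such a batch with the day 8 arrays undecided. A different day or handler stays open.

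More probe sets were lower than higher at day 3, the retina test being set before and the scaling test after the result was seen. Of the lower probe sets 41.1% followed the photoreceptor score (7.48% of others), which leaves the hypothesis of less retina undecided. After median centring 863 were lower and 1509 higher, but centring adds a constant to each array and so sets this outcome itself, which leaves the hypothesis of array scaling undecided. Which of these hypotheses holds stays open.

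Every comparison was refitted to its own arrays alone after exchanging arrays between its groups, a test set before the data were examined except for the 2 added knockout contrasts. The real grouping was the only one with as many calls, 1 of 35 splits, in day 8 against day 3 (3109, highest other 1), IFNAR-KO against WT (12912, highest other 0), IFNγ-KO against WT (14910, highest other 0), infusion against PBS (3159, highest other 0), unstimulated replicates (5121, highest other 0) and knockout against knockout (116, highest other 6). It was 1 of 100 in day 3 (3570, highest other 1866), day 8 (1752, highest other 59), IFNAR-KO against unstimulated (16553, highest other 12) and IFNγ-KO against unstimulated (16306, highest other 6649). In these the real grouping gave the smallest share that the number of splits allows, without correction for the number of comparisons. The splits treat arrays as independent samples. They cannot exclude chance between animals, pools or batches if replicates were technical or processed together. For infusion minus day 8 (868, highest other 0) and the difference of knockout differences (788, highest other 0), in a fit changed after the results were seen, the real grouping was also 1 of 35. The control arrays were not exchanged there, so this does not exclude chance for either difference of responses. For PBS against unstimulated all 100 of 100 splits had at least as many calls as the real 0, an outcome that a count of 0 fixes in advance. Its highest split, 8254, set unstimulated replicates 1 to 4 against the rest, which points to structure of the samples.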
